A study of Rattus norvegicus with 3 samples.

How the data were processed

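Total RNA from rat soleus was extracted with Trizol and purified with an RNeasy kit, and biotin-labelled cRNA was prepared by the Affymetrix protocol, per the labels' protocols. RNA of 4 rats was mixed for each group per the series description, and 1 array was run per group: control, suspension for 7 days and suspension for 14 days. The platform, an Affymetrix rat genome expression array, was read from the annotation table. The source description of the 14-day sample says 7 days, whereas its title and its time entry say 14 days; it was taken as the 14-day sample. The control is described as a control of 7 days, and no 14-day control was used here.

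The deposited values were log2 signals per probe set, which the authors had scaled so that the mean unlogged signal, after trimming 2% at each end, was nearly the same on every array (500.25 in control, 500.248 at 7 days and 500.239 at 14 days). This was read from the values, and the program and settings that made them are not given in the sources used here. The values were not quantile normalized and not centred, and they were used as deposited. Of the 31099 probe sets, 53, 104 and 134 were at 0 on the arrays of control, 7 days and 14 days, and the array medians were 6.77, 6.70 and 6.76. Over 18 hybridization control probe sets the median log2 difference was 0.05 for 7 days against control, 0.02 for 14 days against control and -0.04 between the suspended arrays, and the largest absolute differences were 0.37, 0.46 and 0.26.

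The 57 control probe sets were left out of the gene analysis. Of the other 31042, the annotation gave 1 gene for 20826, several genes for 436 and no gene for 9780; the probe sets of several genes or none were not used for genes. A gene was represented by its probe set of highest mean signal, which left 14217 named genes. Signals under a floor at the 40th percentile of all values, a log2 signal of 6.01 or 64.5 unlogged, were set to the floor, and a gene counted as measured when at least 1 array reached it, which 11249 genes did. Where the dimmer array lay under the floor, the fold is a lower bound and is written "at least".

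The comparisons were 7 days against control, 14 days against control and 14 days against 7 days, each as a difference of log2 signals. No test was made, since no group has a replicate and genes are not replicates. Genes at least 2-fold apart were counted. Technical spread was estimated from 3956 pairs of probe sets of the same gene, as the SD of the log2 difference of a single probe set. It was 0.43, 0.44 and 0.36 for the 3 comparisons at mean signals under 8 and 0.22, 0.24 and 0.17 at signals of 10 and above. Of these pairs, 6.83%, 6.95% and 3.16% were 2-fold apart in their differences. This spread holds no variation between rats or pools.

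For the 33 gene lists fixed before the data were examined, which cover fibre types, sarcomere, protein breakdown, growth, metabolism, stress, matrix and cell type markers, the median log2 difference of the measured members was set against 10000 random lists of the same size matched on mean signal in 20 bins. Members at least 1.5-fold higher or lower were counted. Lists of further immediate early genes, further glucocorticoid targets and tendon cell markers were added after values had been seen and appear in the closing section alone. The overlap of the days was compared with independent lists and with 100 simulations of unchanged arrays that share 1 control, whose noise was set from the difference between the suspended arrays and so also holds real differences between them.

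The genes named in the text followed a rule also fixed beforehand. It took, for each suspended array against control, the 10 genes of largest and the 10 of smallest log2 difference among genes at or above the floor on both arrays, and up to 3 bounds per direction, and likewise 5 per direction for 14 against 7 days. It also took up to 4 members of each list with the largest absolute difference from control, and 14 genes of muscle wasting and fibre type in every case. Predicted loci were passed over, which concerned 1 locus at 7 days. Not every gene that the rule selects is reported here. This gave 175 genes, of which 51 had other probe sets. For 21 of these a further probe set had the opposite sign in at least 1 comparison, and for 1, Pdgfrb, both differences were also at least 1.5-fold in size. Myoz1, Myoz2, Atp2a1, Col4a1, Pdgfra, Pi16, Per2, Mcm2, Gsr and the members of the added lists that the rule does not select were named after their values were seen.

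The procedure was tested on simulated data with the technical spread of 7 days against control. Of 50 genes per size, 10% were called at a true 1.5-fold difference, 90% at 2.83-fold and 100% at 4-fold and at 8-fold, where the floor lowered the mean recovered log2 difference from 3 to 2.70. Of the unchanged genes 0.541% were called, a rate for technical noise alone, as estimated from probe sets at or above the floor on every array. The medians of 36 of 40 unchanged lists lay inside the random range, and 20 of 20 lists shifted by 0.5 lay above it.

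The alternatives tried were centring each array on the median of its measured genes, quantile normalization, a floor at the 25th or 50th percentile, no floor and no filter, the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, and the mean of a list in place of its median. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.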

Results

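Gene expression was measured in the soleus, a slow postural muscle of the hind limb, of Sprague-Dawley rats aged 8 weeks per the labels. Rats with normally loaded limbs were compared with rats whose hind limbs were unloaded by suspending the tail at an angle of about 30 degrees, a ground model of weightlessness, for 7 or 14 days. The RNA of 4 rats was pooled for each of the 3 groups, and each pool was hybridised to 1 Affymetrix rat expression array of 31099 probe sets. Every value therefore comes from 1 array per group, holds no measure of the spread between rats, and is given without a test. The number of arrays limits the precision of all comparisons.

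The arrays were of like quality. The share of probe sets at or above the signal floor, a log2 signal of 6.01, was 61.6% in control, 59.1% at 7 days and 59.3% at 14 days. The 3' probe set of Gapdh exceeded its 5' probe set by a log2 difference of 0.25, 0.24 and 0.20 on the same arrays, and that of beta-actin by 1.16, 1.21 and 1.25, so RNA integrity differed little. Over 16546 probe sets at or above the floor on every array, the correlation across probe sets was 0.979 between the suspended arrays, against 0.967 and 0.960 between control and the arrays of 7 and 14 days. Probe sets are not independent replicates. Pairs of probe sets of the same gene gave the only measure of error, which is technical: the log2 difference of a single probe set had an SD of 0.37 for 7 days against control, 0.38 for 14 days against control and 0.30 between the suspended arrays.

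The first comparison asks which genes differed in the soleus after a week without load. After 7 days of suspension, 6 of 15 measured fast fibre genes stood at least 1.5-fold above control and none stood as far below it, with a list median of 1.49-fold. Myh4, the myosin heavy chain of type IIB fibres, was 76.4-fold higher, with a log2 signal of 8.62 in control and 14.88 in the suspended pool. The latter lies near the highest value on that array, 16.03, so the fold may be compressed. Actn3, the alpha-actinin of fast fibres, was 17.6-fold higher. Ankrd1, a titin-binding protein that responds to stretch, was 8.10-fold lower, and a further probe set of the gene gave a log2 difference of -2.99. Cebpd and Ddit4, which are induced in wasting muscle, were 5.38-fold and 3.75-fold higher.

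Among the other genes with the largest differences at 7 days, Pck1, the cytosolic enzyme that makes phosphoenolpyruvate from oxaloacetate, was 11.2-fold higher, and Gadd45g, a gene induced by stress and growth arrest, was 8.73-fold higher. Mybpc2, the fast form of myosin-binding protein C, was 5.59-fold higher, Aqp4, a water channel of the fibre membrane, 5.52-fold, and Fbp2, the muscle fructose bisphosphatase, 4.62-fold. Nagpa, an enzyme that finishes the sorting tag of lysosomal proteins, was 4.67-fold higher at a low control signal of 6.21. Rpl39 was 4.58-fold higher at a low control signal of 6.96. For Myh8, the perinatal myosin heavy chain, the control signal lay under the floor and the difference was at least 14.2-fold. By the same reckoning C8h3orf18 was at least 6.48-fold higher and Gpt2, a mitochondrial alanine aminotransferase, at least 5.43-fold higher.

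On the lower side at 7 days, Hbegf, a ligand of the epidermal growth factor receptor, was 6.42-fold lower and Igdcc3 5.31-fold lower. Mettl21c, a lysine methyltransferase of muscle, was 4.68-fold lower, Mllt11 4.40-fold, the nuclear exportin Xpo4 4.28-fold and the protease Tasp1 3.89-fold. Tnfrsf12a, the receptor of the cytokine TWEAK, was 4.17-fold lower and Enah, a regulator of actin filaments, 3.92-fold lower. The suspended signal lay under the floor for Bdh1, a mitochondrial enzyme of ketone body use, at least 5.84-fold lower, for Doc2g, at least 5.35-fold lower, and for the transcription factor Bcl11a, at least 5.18-fold lower.

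Among the fixed gene lists, fast fibre genes had a median log2 difference of 0.57 at 7 days, against a range of -0.18 to 0.20 for 10000 random lists matched on expression, with 2.5% of the random medians left out at each end, as a description of these arrays. Of the 15 measured members, 6 were at least 1.5-fold higher and none was 1.5-fold lower, among them Pvalb, the calcium buffer of fast fibres, at 3.61-fold. Slow fibre genes had a median of -0.11, inside their random range, with 2 of 13 members at least 1.5-fold lower: the calsequestrin Casq2 (2.03-fold) and the stretch-responsive Ankrd2 (1.92-fold). The slow myosin heavy chain Myh7 differed by 0.02 at a signal of 15.81 in control, close to the highest value on that array, 15.94, where a difference is compressed, and a further Myh7 probe set of lower signal gave -0.50. Most other slow fibre genes also lay near that value in control, such as Tnnc1 at 15.74 and Atp2a2 at 15.68. The median of the slow fibre list may therefore understate a difference. Myh2, of type IIA fibres, differed by 0.08 at a control signal of 15.35, also near the top, and Myh1, of type IIX fibres, by -0.52. The structural genes of the sarcomere had a median of 0.01, a sign that turned under both other scalings, with Tmod1 2.79-fold higher and Xirp1, an actin-binding protein of loaded muscle, 3.18-fold lower. Several sarcomere genes also lay near the top in control, such as Acta1 at 15.74 and Actn2 at 15.61. Their median may therefore hide a difference.

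Genes known from muscle atrophy were higher together at 7 days. Their median was 0.42 (random range -0.17 to 0.20), and 7 of 21 members were at least 1.5-fold higher with none as much lower. The muscle ubiquitin ligases Fbxo32 and Trim63 were 2.40-fold and 1.88-fold higher, Fbxo32 at a low control signal of 6.48 with a technical SD of 0.43. Eif4ebp1, a repressor of translation initiation, was 1.98-fold higher. Proteasome subunits had a median of 0.08, inside their range, although the activator subunit Psme1 was 1.86-fold higher. Mstn, a secreted inhibitor of muscle growth, stayed under the floor on every array, with log2 signals of 1.73, 5.01 and 4.91. Growth and myogenic genes had a median of 0.27 (range -0.16 to 0.20), with members in both directions: Igfbp3, a carrier of insulin-like growth factors, was 2.76-fold higher, Fst, an antagonist of activins, 2.13-fold, Myod1 1.93-fold and Igf1 1.48-fold, while the myogenic factor Myog was 2.39-fold lower and the activin subunit Inhba 2.25-fold lower. Medians inside their random ranges were also seen for autophagy and lysosome genes (-0.04), calpain and apoptosis genes (-0.05) and neuromuscular junction and denervation genes (-0.04), the last with the acetylcholine receptor subunit Chrnd 2.10-fold lower and the transcription factor Runx1 1.97-fold lower.

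Metabolic lists parted at 7 days. Glycolysis and glycogen genes had a median of 0.41 (range -0.17 to 0.21) and 5 of 17 members at least 1.5-fold higher. Fatty acid uptake and oxidation genes had a median of -0.39 (range -0.15 to 0.15), with 22 of 25 members below control. Among them were Cpt2 (1.84-fold lower) and the carnitine carrier Slc25a20 (1.63-fold lower). The uncoupling protein gene Ucp3 was 1.82-fold higher, although a further Ucp3 probe set of lower signal gave a log2 difference of 0.20. Oxidative phosphorylation genes were lower by a small amount across the list: 48 of 51 lay below control, with a median of -0.17 (range -0.11 to 0.09). Genes of the tricarboxylic acid cycle had a median of -0.22 (range -0.18 to 0.19). Regulators of mitochondrial genes had a median of -0.13, inside their range, with the deacetylase Sirt3 2.14-fold lower, the coactivator Ppargc1a at a log2 difference of -0.32 and Prkag3, an AMP-activated kinase subunit of glycolytic fibres, 3.38-fold higher.

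Chaperone and stress lists were lower at 7 days. Heat shock genes had a median of -0.22 (range -0.16 to 0.18), with 16 of 18 below control. Hspa1a was 2.48-fold, Hspa2 2.47-fold and Hsph1 2.09-fold lower. The small heat shock genes Hspb1 and Cryab differed by -0.21 and -0.13. Their control signals, 15.17 and 15.63, lay near the top of the scale, so these differences may be compressed. Redox genes had a median of -0.24 (range -0.15 to 0.18), with the quinone reductase Nqo1 2.44-fold lower, and inflammatory and NF-kappaB genes a median of -0.33 (range -0.23 to 0.24), with the chemokine Ccl2 2.33-fold lower and Il15 and the inhibitor Nfkbia 2.53-fold and 2.49-fold higher. Cytosolic ribosomal protein genes lay above control in 38 of 39 cases, by a median of 0.30 (range -0.13 to 0.11). Circadian genes (-0.11), cell cycle genes (0.18), translation factors (-0.01) and reference genes (0.20) had medians inside their ranges, with Per1 2.54-fold and Mki67 2.09-fold higher.

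Markers of other cell types also differed between the 7-day pool and control. Macrophage markers had a median of 0.56 (range -0.20 to 0.24), and 14 of 15 lay above control, among them the scavenger receptor Cd163 (2.11-fold) and C1qc (1.90-fold). Adipocyte markers had a median of 0.59 (range -0.28 to 0.31), with the desaturase Scd 3.97-fold higher, and mast cell markers a median of 0.56 (range -0.47 to 0.47) over 5 measured genes, with Cpa3 1.87-fold higher, although with no floor and no filter the mast cell median was -0.25. Fibroblast and tendon markers had a median of -0.27 (range -0.21 to 0.24) with members in both directions, 5 of 12 at least 1.5-fold lower and 3 at least 1.5-fold higher: the tendon cell genes Scx and Tnmd were 2.21-fold and 2.16-fold lower, and the fibroblast genes Pdgfra and Pi16 were 1.82-fold and 1.57-fold higher. Extracellular matrix genes had a median of 0.01, whose sign turned under both other scalings, with the tendon and matrix protein Tnc 2.16-fold lower. Endothelial (-0.12), smooth muscle (-0.14), lymphocyte (-0.27), nerve and Schwann cell (0.39), red blood cell (-0.06) and satellite cell (-0.20) markers had medians inside their ranges.

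Of the 11249 measured genes, 251 were at least 2-fold higher and 270 at least 2-fold lower at 7 days, 39 and 51 of them as bounds against the floor, so 48.2% of these genes were higher; with each array centred on its median, 37.5% were higher. These genes are 4.63% of those measured, where simulated unchanged arrays gave 0.541% with technical noise alone and 3.62% with noise as large as the whole difference between the suspended arrays. The technical noise was measured on probe sets at or above the floor on every array, so its rate may be too low for genes near the floor. The medians of 8 lists lay above and of 7 lists below their random ranges, where 0.825 of 33 lists of unrelated genes would lie on each side. Genes of a list can shift together on 1 array or in 1 pool, so that number does not measure chance for these lists.

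**Figure D1:**
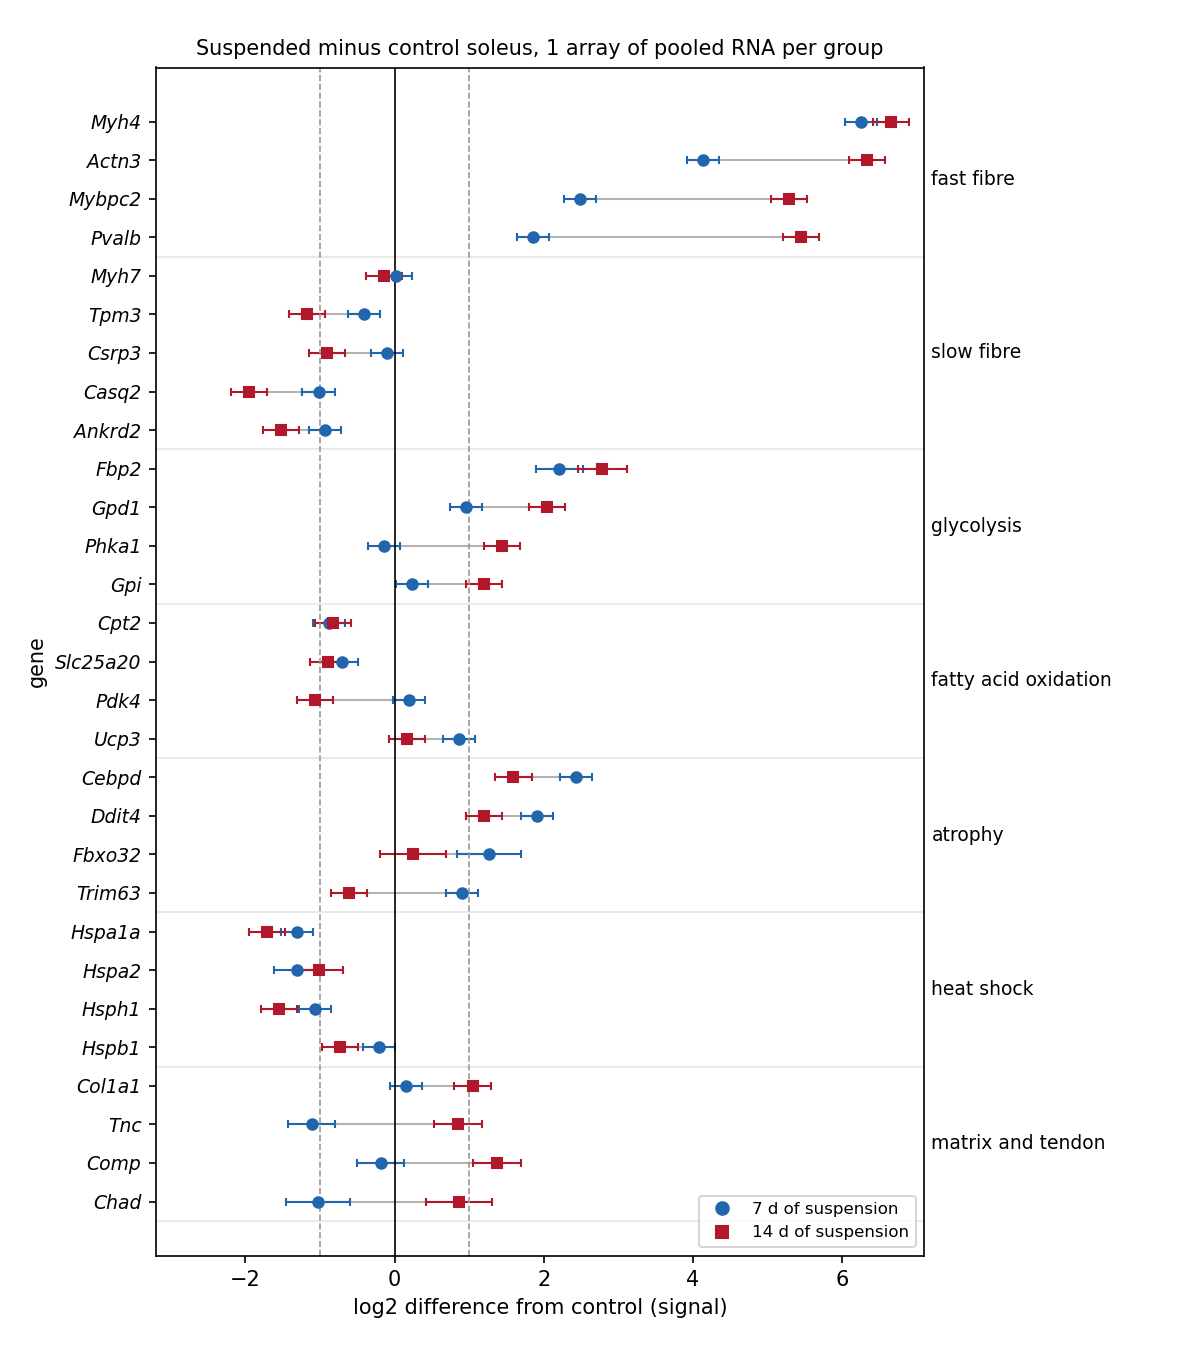
Log2 difference in signal from control (horizontal axis) for named genes (vertical axis), grouped by list, after 7 days (circles) and 14 days (squares) of suspension, 1 array per group. Bars are the technical SD of a single probe set at that expression level, and dashed lines mark a 2-fold difference; Myh4 lies at 6.26 and 6.66, whereas Trim63 lies above control at 7 days (0.91) and below it at 14 days (-0.61).

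After 14 days of suspension, 7 of 15 fast fibre genes stood at least 1.5-fold above control and 5 of 13 slow fibre genes stood at least 1.5-fold below it. Myh4 was 101-fold above control, Actn3 80.5-fold, Pvalb 43.8-fold and Mybpc2 39.2-fold, with 14-day signals from 14.83 to 15.28, close to the top of the scale. Fhl2, a LIM-domain protein of the sarcomere, was 7.64-fold lower and Mettl21c 10.9-fold lower. Of the 32 extracellular matrix genes 24 lay above control, among them Col1a1 (2.06-fold), and 8 below it, among them Col4a1 (1.31-fold) and Timp1 (1.42-fold); of the 12 fibroblast and tendon markers Comp was 2.60-fold higher, Scx 1.65-fold lower and Tnmd differed by 0.03. Fbxo32 lay 1.18-fold above control, at low signals of 6.48 in control and 6.72 at 14 days.

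Further genes with the largest differences at 14 days were Cd24, a surface glycoprotein (11.7-fold higher), Aqp4 (8.12-fold), Ky, a muscle peptidase linked to kyphoscoliosis (8.07-fold), and Fbp2 (6.90-fold). Atp1b2, a beta subunit of the sodium pump, was 6.22-fold higher and Cish, a suppressor of cytokine signalling, 5.83-fold higher. With control under the floor, Gpt2 was at least 14.6-fold, C8h3orf18 at least 8.95-fold and the potassium channel gene Kcnc1 at least 5.42-fold higher. Lower than control were Hba-a3, an alpha-globin gene (6.94-fold), Xpo4 (5.87-fold) and Ak4, a mitochondrial adenylate kinase (5.08-fold). The transcription factor genes Fos and Maff were 4.76-fold and 4.53-fold lower, the glycerol channel Aqp7 4.71-fold and Hbegf 4.43-fold. With the suspended signal under the floor, Bcl11a was at least 5.18-fold, Csrnp1 at least 4.74-fold and Inpp5j, an inositol phosphatase, at least 4.25-fold lower.

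Fast fibre genes had a median of 0.53 at 14 days (random range -0.28 to 0.08), with 7 of 15 members at least 1.5-fold higher. Slow fibre genes had a median of -0.35 (range -0.29 to 0.10), or -0.63 with the mean of a gene's probe sets, and a list mean of -0.60. Of the 13 members, 12 lay below control and 5 were at least 1.5-fold lower, namely Casq2 (3.87-fold), Ankrd2 (2.88-fold), the slow tropomyosin Tpm3 (2.27-fold), the Z-disc protein Csrp3 (1.87-fold) and Myoz2 (log2 difference -0.63). For Tpm3, 11 further probe sets of lower signal gave log2 differences from -1.58 to 0.41. Myh7 differed by -0.14 near the top of the scale and by -1.23 in its further probe set. Most other slow fibre genes also lay near the top in control, so their differences may be compressed too. Myh2 differed by -0.07 and Myh1 by -0.56. Sarcomere genes had a median of -0.18, inside their range, with Myom2 2.52-fold higher, Xirp1 3.56-fold lower and Lmod2 at a log2 difference of -1.32. Several sarcomere genes lay near the top of the scale in control, so this median may understate a difference.

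The metabolic lists lay further apart at 14 days. All 17 measured glycolysis and glycogen genes lay above control, 10 by at least 1.5-fold, with a median of 0.79 (range -0.25 to 0.11). Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, was 4.13-fold higher, the phosphorylase kinase subunit Phka1 2.71-fold and Gpi 2.29-fold. Fatty acid genes lay below control in 24 of 25 cases, with a median of -0.54 (range -0.22 to 0.08) and with Pdk4, the kinase that switches off pyruvate dehydrogenase, 2.09-fold lower. Oxidative phosphorylation genes had a median of -0.25 (range -0.19 to -0.02), and of -0.15 under quantile normalization. The range was drawn from the values as deposited. None was drawn under quantile normalization, so whether -0.15 would lie outside its random range there is not known. Tricarboxylic acid cycle genes had a median of -0.19, inside their range, and regulators of mitochondrial genes -0.47 (range -0.20 to 0.25), among them Esrrb (2.67-fold lower), Esrrg (2.13-fold lower) and Ppargc1a (1.80-fold lower).

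Heat shock genes lay below control in 18 of 18 cases at 14 days, with a median of -0.65 (range -0.24 to 0.13). Hspa1a was 3.29-fold lower, Hsph1 2.92-fold, Hspb1 1.67-fold and Cryab 1.36-fold. For Hspb1 and Cryab the control signal lay near the top of the scale, so these folds may be compressed. Redox genes had a median of -0.33 (range -0.19 to 0.15), with the metallothionein Mt2A 3.56-fold and the sulfiredoxin Srxn1 2.48-fold lower, and inflammatory genes a median of -0.27 (range -0.22 to 0.31). Neuromuscular junction and denervation genes had a median of -0.32 (range -0.23 to 0.30), with Chrnd 3.88-fold and Runx1 2.53-fold lower. The atrophy list had a median of 0.10, inside its range and of turned sign (-0.01) under median centring: Cebpd (3.02-fold) and Ddit4 (2.29-fold) were above control, while Trim63 was 1.52-fold lower. Myod1 was 3.60-fold higher and Myog 2.02-fold lower, in a growth list whose median of 0.12 lay inside its range, and Igf1 was 1.76-fold higher. Cell cycle genes had a median of 0.48 (range -0.25 to 0.31), with the cyclin Ccna2 2.11-fold higher.

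Cell type markers at 14 days again had a macrophage median of 0.56 (range -0.20 to 0.28), with 7 of 15 members at least 1.5-fold higher, among them Cd14 (2.01-fold). Fibroblast and tendon markers, below control at 7 days, had a median of 0.50 (range -0.27 to 0.23), and extracellular matrix genes, at 0.35 (range -0.17 to 0.11), had 8 of 32 members at least 1.5-fold higher. The 4 measured nerve and Schwann cell markers had a median of 0.78 (range -0.39 to 0.47), with the myelin gene Mbp 2.20-fold higher, and satellite cell markers a median of -0.42 (range -0.40 to 0.50) over 5 genes, with Sdc4 2.23-fold lower. Adipocyte (0.26), mast cell (0.20), smooth muscle (0.23), lymphocyte (-0.35) and red blood cell (-0.45) medians lay inside their ranges, as did those of proteasome subunits (-0.11), calpain and apoptosis genes (-0.23), circadian genes (-0.09), translation factors (-0.08) and reference genes (-0.10). The medians of autophagy genes (0.06), ribosomal proteins (-0.02) and endothelial markers (0.04) also lay inside, with a sign that turned under at least 1 other scaling.

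At 14 days 395 genes were at least 2-fold higher and 274 at least 2-fold lower than control, 56 and 50 of them as bounds, so 59.0% were higher; with each array centred on its median, 42.8% were higher. These genes are 5.95% of those measured, against 3.60% in the simulation with the larger noise. The medians of 7 of the 33 lists lay above and of 9 below their random ranges. The labels name a control of 7 days, so time in the experiment was not matched at 14 days. They give an age of 8 weeks for every group, and whether age at collection was matched is not known.

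**Figure D2:**
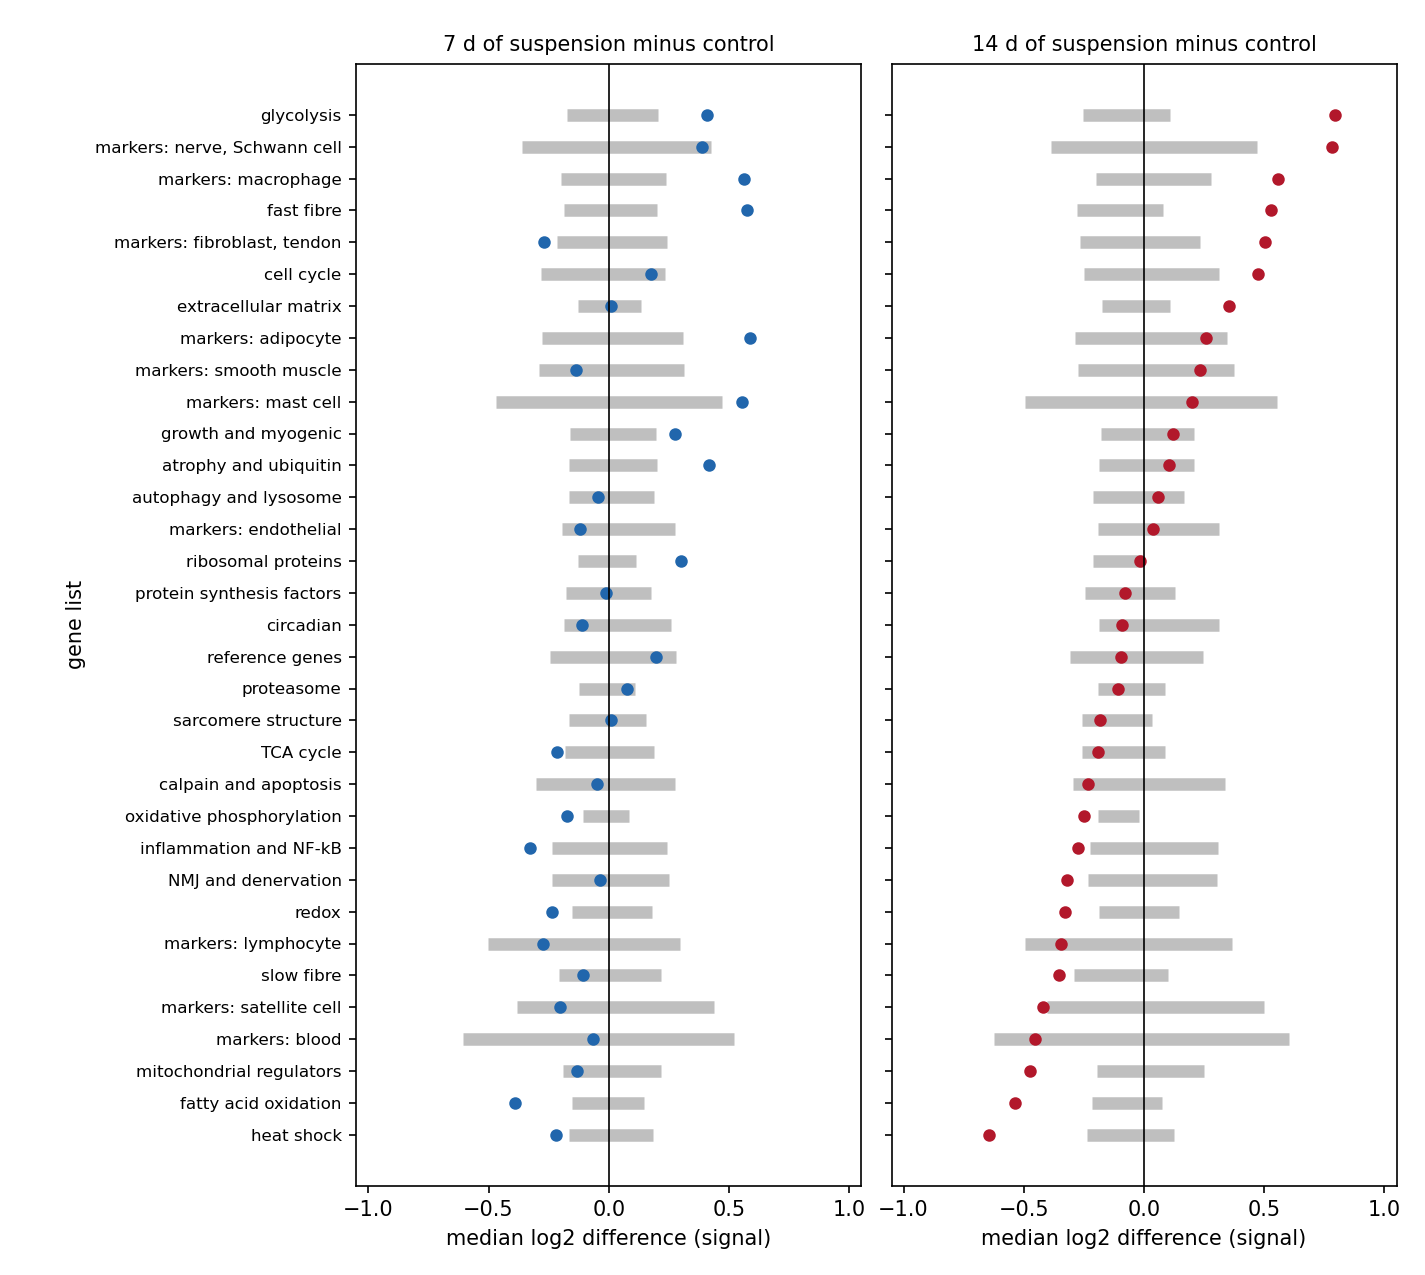
Median log2 difference in signal from control (horizontal axis) of the 33 fixed gene lists (vertical axis) at 7 days (left) and 14 days (right) of suspension. Points are list medians, and grey bars hold the medians of 10000 random lists matched on expression, with 2.5% left out at each end; glycolysis lies at 0.41 and 0.79, and heat shock at -0.22 and -0.65.

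The comparison of the suspended pools with each other asks how expression differed between the shorter and the longer suspension. The list medians of glycolysis, extracellular matrix and fibroblast and tendon genes were higher at 14 days, and those of ribosomal protein and atrophy genes were lower. Pvalb was 12.1-fold, Cd24 8.73-fold, Ankrd1 7.24-fold, Mybpc2 7.01-fold and Padi2, an arginine deiminase, 6.63-fold higher at 14 days. Lower at 14 days were Hba-a3 (5.62-fold), the perinatal myosin Myh8 (5.41-fold), Rpl39 (4.21-fold), the thyroid hormone-binding Crym (3.76-fold) and the embryonic myosin Myh3 (3.69-fold). Myh4 was 1.32-fold higher at 14 days, with both signals near the top of the scale.

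By list, the difference between the suspended arrays was positive for fibroblast and tendon markers (median 0.71, random range -0.19 to 0.14), glycolysis genes (0.47, range -0.19 to 0.06), nerve and Schwann cell markers (0.43, range -0.29 to 0.29), extracellular matrix genes (0.32, range -0.13 to 0.06), smooth muscle markers (0.29, range -0.20 to 0.27) and fast fibre genes (0.11, range -0.21 to 0.04, 8 of 15 higher, and 0.26 under quantile normalization or 0.055 under median centring). It was negative for ribosomal proteins (-0.32, 39 of 39 lower, and -0.18 under quantile normalization), atrophy genes (-0.30, 10 of 21 at least 1.5-fold lower), slow fibre genes (-0.30, 13 of 13 lower), heat shock genes (-0.25), proteasome subunits (-0.22, 31 of 33 lower), fatty acid genes (-0.19, and -0.085 under quantile normalization), mitochondrial regulators (-0.15), neuromuscular genes (-0.36, with a list mean of -0.14), mast cell markers (-0.40) and adipocyte markers (-0.27), each median below its random range. Within these lists Trim63 was 2.86-fold and, at low signals, Fbxo32 2.03-fold lower at 14 than at 7 days, Tnc 3.91-fold and Comp 2.95-fold higher. Medians of the other lists lay inside their ranges, and those of oxidative phosphorylation (-0.06), the tricarboxylic acid cycle (0.04), redox genes (-0.04) and translation factors (-0.10) turned sign under at least 1 other scaling.

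Between the suspended arrays 162 genes were at least 2-fold higher and 92 at least 2-fold lower at 14 days, so 63.8% were higher; with each array centred on its median, 53.5% were higher. The technical spread was also lowest for this pair of arrays, at an SD of 0.30 for a single probe set.

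Genes at least 2-fold from control overlapped between the days. At least 2-fold from control were 140 genes higher at both, 120 lower at both and 1, Padi2, lower at 7 days and higher at 14, while 260 passed 2-fold at 7 days alone and 408 at 14 days alone. Independent lists of these sizes would share 8.81 higher and 6.58 lower genes. Both comparisons use the same control array, however, and in 100 simulations of unchanged arrays 29.9 genes were higher at both and 98.0 lower at both on average, 1.28 went opposite ways, 278 passed 2-fold at 7 days alone and 276 at 14 days alone. With each array centred on its median, 182 genes were lower at both days. The covariance of the log2 differences across genes was 0.184, against 0.0978 in the simulations (highest 0.107), an excess of 0.0864, and the correlation was 0.72 against 0.50. The simulations gave every array the same noise, set from the suspended arrays. The technical SD was larger in the comparisons with control, 0.37 and 0.38, than between the suspended arrays, 0.30. Whether the simulated noise of the shared control was large enough is not known. With 1 control array the control could not be split, and part of the excess overlap and covariance may come from it.

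**Figure D3:**
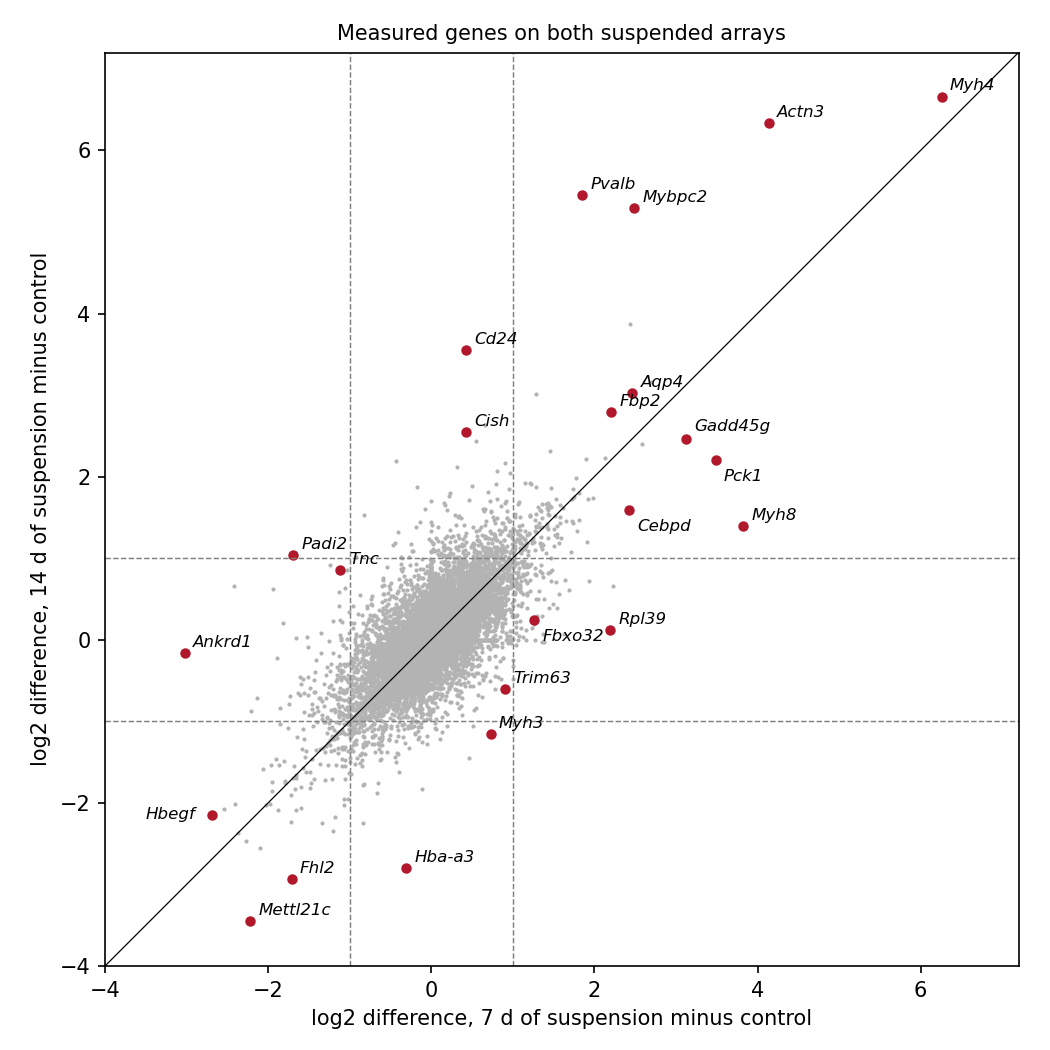
Log2 difference in signal from control at 7 days (horizontal axis) and 14 days (vertical axis) of suspension for the 11249 measured genes (grey points), values under the floor set to it, with named genes in red. Dashed lines mark a 2-fold difference and the solid line equal differences; Pvalb lies at 1.85 and 5.45, above that line, and Pck1 at 3.49 and 2.20, under it.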

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

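The tests of carry-over, of scaling, of tendon content and of fibre share were chosen only after the result was seen, and all but that of tendon content were also revised, those of carry-over and scaling from fewer genes to all 6, that of carry-over for signals near the top of the scale, and that of fibre share from 3 other cell types to all those with markers; the test of immediate early genes was chosen before its values were seen, except for the comparison with the members' SD, which was added afterwards.

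Several results lay in opposite directions at 7 and 14 days against control, and for each of them the difference was not tested. The log2 difference at 14 days exceeded that at 7 days by 1.69 for Bhlhe41, a repressor in the circadian clock, by 1.89 for Chad, a cartilage and tendon matrix protein, by 2.73 for Padi2, by 1.97 for Tnc and, with the 7-day signal under the floor, by at least 3.08 for Doc2g. It was lower at 14 than at 7 days for Myh3, at -1.88, and for Trim63, at -1.52. The median of the fibroblast and tendon markers at 14 days exceeded that at 7 days by 0.77. Among 5139 measured probe sets with no gene name, which no comparison of genes used, 63 were at least 2-fold above control at both days and 62 at least 2-fold below.

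Of the fast fibre genes, 6 were at least 1.5-fold above control at both days: Myh4, Actn3, Mybpc2, Pvalb, Atp2a1 and Myoz1. For the scaling of the arrays, the smallest median of the 6 genes over both days and 2 other normalizations was 2.10, above the 0.58 of a 1.5-fold difference. The 6 genes were picked for their differences in these same data, and centring moved differences by 0.12 at most. The test could therefore hardly have failed, and no conclusion is drawn from it. All 15 fast fibre genes had medians of 0.51 at 7 days and 0.41 at 14 days under median centring. Under quantile normalization these were 0.53 and 0.63. Carry-over of a neighbouring fast muscle cannot be told apart from a change in the soleus: the control-subtracted log2 ratios of 14 over 7 days had a range of 3.86 over the 6 genes, where a common factor and the technical spread allow up to 1.28, but their 14-day signals, 14.76 to 15.28, lie close to the top of the scale, where compression gives unequal ratios as well. Suspension itself stays open as well and was not tested, since each group has 1 array.

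Connective tissue genes were higher at 14 than at 7 days, with the fibroblast and tendon markers at a median of 0.71. More tendon in the 14-day pool may account for this: 6 tendon markers had a median of 1.25 against an upper random value of 0.25, although all 6 also belong to the list that showed the pattern, and 6 of 6 lay below control at 7 days (median -0.93) and 5 of 6 above it at 14 days (median 0.53). The most abundant of them, Thbs4 and Tnmd, had log2 signals of 12.94 and 12.57 in control, 12.11 and 11.46 at 7 days and 13.15 and 12.59 at 14 days. A smaller share of muscle fibres alone would raise the markers of every other cell type alike, but between these pools they did not move alike. Adipocyte markers had a median of -0.27 (8 of 8 lower, random range -0.22 to 0.24, bootstrap SE 0.0852). They lay 0.978 under the fibroblast and tendon median (bootstrap SE 0.387). Mast cell markers had a median of -0.40. Nerve and Schwann cell (0.43), smooth muscle (0.29) and endothelial markers (0.17) were higher. The first 2 of these lay 0.278 and 0.422 from the fibroblast and tendon median (bootstrap SE 0.388 and 0.418). These SEs resample marker genes, which are not replicates, and hold no error between pools. No conclusion on the share of fibres is therefore drawn from them. Among the adipocyte markers, a further Plin1 probe set of low signal was higher at 14 than at 7 days, by 0.61. A smaller fibre share joined to a loss of adipocytes and mast cells, and a response of connective tissue to longer suspension, were not tested and stay open.

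Stress-inducible genes such as Fos, Maff and Hbegf were lower on both suspended arrays, as were 16 of 18 heat shock genes at 7 days, 6 of them by at least 1.5-fold, and 18 of 18 at 14 days. Handling or collection could give a wide immediate early response in the control pool. For it, the other immediate early genes were predicted at or below -0.58, a chosen cut-off of 1.5-fold. The 17 measured had a median of 0.071 at 7 days (random range -0.22 to 0.23) and 0.10 at 14 days. The genes that had shown the pattern were left out of this list, so its median does not cover them. A response weaker than the cut-off also stays open. Against the spread of single members the margin was narrow. The gap to the cut-off was 0.656 at 7 days and 0.682 at 14 days. It exceeded the members' SD at 7 days (0.644) but not at 14 days (0.744). That SD does not measure the error of the median, whose bootstrap SE over the members was 0.13 at 7 days and 0.12 at 14 days. A response limited to a few genes stays open, since Fosb (-1.13, bounded by the floor), Junb (-0.70) and Nr4a3 (-0.85) were also lower at 7 days while Ier3 (1.31) and Zfp36 (1.04) were higher. Suspension itself was not tested and stays open.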

How the results depend on the processing

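All alternatives were fixed beforehand. Of the comparisons of a value with its alternatives, 29 of the counts stayed within 1.5 times their value and 31 did not; 622 list medians moved by less than the SE of a bootstrap over their members, 70 moved by more, and 1 that lay outside its random range turned sign; and 3029 values of named genes moved by less than the technical SD and 112 by more. Several medians inside their random ranges also turned sign under another scaling, as given beside them in the results. No array could be left out, since each group has 1. Signals near the floor set the limit of the counts, as the counts under other floors show.

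The 2-fold counts follow from the threshold and the floor by construction. At 1.5-fold, 1021 genes were higher and 1034 lower at 7 days, 1316 and 1045 at 14 days, and 730 and 484 at 14 against 7 days. At 3-fold the counts were 37 and 49, 72 and 48, and 30 and 6. With the floor at the 25th percentile, 470 genes were higher and 665 lower at 7 days, 614 and 695 at 14 days, 365 and 288 at 14 against 7 days, and 241 higher and 334 lower at both days. With the floor at the 50th percentile, 94 were higher and 58 lower at 14 against 7 days. With no floor and no filter, 1047 were higher and 1505 lower at 7 days, 1237 and 1587 at 14 days, 1179 and 1077 at 14 against 7 days, and 576 higher and 735 lower at both days. With neither, the lists also took in annotated markers that had not counted as measured. The mast cell list then held 7 genes in place of 5, and the nerve and Schwann cell list 8 in place of 4. With these members the mast cell median at 7 days reversed to -0.25. The nerve and Schwann cell median at 14 against 7 days was 0.30.

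Centring each array on its median moved the differences by -0.07 at 7 days, -0.12 at 14 days and -0.05 at 14 against 7 days, and 182 genes were then lower at both days. Under it the medians at 7 days were -0.24 for oxidative phosphorylation, -0.28 for the tricarboxylic acid cycle, -0.45 for fatty acid genes and 0.23 for ribosomal proteins. At 14 days they were -0.36 for oxidative phosphorylation, -0.65 for fatty acid genes, 0.24 for extracellular matrix, -0.45 for redox, 0.36 for cell cycle, -0.39 for inflammatory genes and 0.44 for macrophage markers. At 14 against 7 days they were -0.27 for the proteasome and -0.37 for ribosomal proteins. These shifts follow from the centring.

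Under quantile normalization the medians were -0.23 for oxidative phosphorylation and 0.23 for ribosomal proteins at 7 days, and -0.15 for oxidative phosphorylation, -0.46 for fatty acid genes and -0.25 for redox at 14 days. At 14 against 7 days they were -0.18 for the proteasome, -0.085 for fatty acid genes, -0.19 for heat shock and -0.18 for ribosomal proteins. With the mean of a gene's probe sets, the tricarboxylic acid cycle stood at -0.30, fatty acid genes at -0.25 and ribosomal proteins at 0.28 at 7 days, slow fibre genes at -0.63 at 14 days, and nerve and Schwann cell markers at 0.30 at 14 against 7 days. For these results the cause was not tested.

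With the mean of a list in place of its median, values at 7 days were 1.27 for fast fibre, 0.60 for atrophy, -0.30 for fatty acid, -0.44 for heat shock and 0.33 for ribosomal protein genes. At 14 days they were 1.94 for fast fibre, -0.60 for slow fibre, -0.22 for oxidative phosphorylation and 0.27 for extracellular matrix genes. At 14 against 7 days they were 0.67 for fast fibre, -0.14 for neuromuscular junction, -0.26 for fatty acid, 0.39 for extracellular matrix and -0.36 for ribosomal protein genes. Mean and median differed in sign at 7 days for autophagy (mean 0.03), extracellular matrix (-0.11), translation factors (0.01) and smooth muscle markers (0.01), at 14 days for reference genes (0.05), mast cell markers (-0.06) and the added immediate early genes (-0.02), and at 14 against 7 days for calpain and apoptosis genes (0.03) and immediate early genes (-0.04). The cause was not tested.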

Other observations

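The test of glucocorticoid targets was chosen before its values were seen; the members named there were picked after their values were seen.

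Members of some lists went different ways. Among circadian genes, Per1 was 2.54-fold higher at 7 days and 2.26-fold higher at 14 days, whereas Dbp, an output gene of the clock, was 1.73-fold and 2.40-fold lower and Per2 1.57-fold and 1.85-fold lower. Among cell cycle genes, Mcm6 and Mcm2, parts of the replicative helicase, were 2.33-fold and 1.81-fold higher at 7 days, whereas the cyclin Ccnd2 was 2.31-fold lower at 7 days and 1.60-fold lower at 14 days. Among globin genes at 14 days, Hba-a3 was 6.94-fold lower while the beta-globin gene Hbb had a log2 difference of -0.13.

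All 4 measured nerve and Schwann cell markers lay above control at both days, with the myelin gene Pmp22 1.33-fold higher at 7 days and 1.95-fold higher at 14 days. All 8 adipocyte markers were lower at 14 than at 7 days, and Plin1, the coat protein of lipid droplets, was 2.19-fold and 1.91-fold above control at 7 and 14 days. A further Plin1 probe set of lower signal, under the floor in control, gave log2 differences of at least 0.63 and 1.24. By that probe set Plin1 was higher at 14 than at 7 days, by 0.61. The redox genes Gsr and Gsta4 were 1.74-fold and 1.66-fold lower at 7 days.

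Cebpd, Ddit4, Pck1 and Per1, genes that glucocorticoids induce, were higher at 7 days, and a glucocorticoid response in the suspended rats was put as a hypothesis. Further glucocorticoid targets, 10 measured, had a median of 0.60 at 7 days against an upper random value of 0.27, with 9 of 10 above control, so the values the hypothesis needs were there, and such a response may have taken part. Arrdc2 was 3.23-fold, Pik3r1 2.56-fold and Sgk1 2.22-fold higher, whereas Cdkn1c differed by -0.47. At 14 days the median was 0.20, inside its random range (-0.27 to 0.28), and at 14 against 7 days it was -0.42. Of the 10, 1 (Klf15) also belongs to the atrophy list, and several are induced by other signals as well, so the test does not single out glucocorticoids.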
